A study of Rattus norvegicus with 21 samples.

How the data were processed

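Gene expression was measured in the retina of male Long Evans rats, a pigmented strain, after streptozotocin (STZ), a toxin of the insulin-producing beta cells. Rats received 65 mg/kg STZ or buffer, and the labels count as diabetic those with blood glucose above 250 mg/dl at 48 h. Each of the 21 arrays was hybridized with RNA pooled from 1 retina of each of 3 rats. The 7 groups (diabetic and buffer-injected control at days 7, 28 and 84, and STZ-injected rats that stayed normoglycemic at day 7) held 3 arrays and 9 rats each. An array is therefore the unit of replication, and its value already averages 3 animals.

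The deposited scanner files of each array hold spot intensity of a 1-colour rat design with 45018 spots, 43379 of them not controls. Per the file headers they were made with Agilent Feature Extraction 9.1.3.1, under an earlier extraction protocol for 2 arrays and a later one for 19. The signal intensity used here was the deposited background-subtracted, spatially detrended value, which carries no scaling between arrays. The deposited raw mean spot intensity and median local background intensity were used for an alternative background correction. The submitters also deposited a value table in log2 units, made by the authors by a method that the labels do not state. Its 41090 rows matched 41012 of the probes read here and left 78 unmatched. Differences between arrays in that table correlated with those of the scanner files at a median r of 0.929 over 210 array pairs (lowest 0.652), with slopes of 0.645 to 1.29. Its columns have medians of -0.09 to 0.07, and 50.1% of its probes have a median over the arrays within 0.1 of 0. Whether and to what reference probes were centred, and part of the scaling, remain unknown, so the table served only as an alternative.

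Signals were taken to log2, spots that the scanner software marked as outliers were left out, spots of the same probe were averaged, and the 75th percentile of each array was subtracted. Values are therefore log2 signal relative to that percentile of the same array. Probes well above background on at least 3 of the 21 arrays were tested, 34588 of 41012. A total of 742 values were missing among 714 of the tested probes, which were left out of the list tests. The files name probes by accession, symbol or description. A gene symbol was assigned from the accession for 10667 probes, from a current symbol for 5537, from a synonym for 3725 and from the file's own name for 190, and 20893 had none. Of the tested probes, 17500 had a symbol. They covered 13204 genes in the list tests, each by the probe with the highest mean signal. The files give no chromosome positions and no genome was supplied, so none are stated.

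The 12 comparisons were diabetic against control at each day and over the mean of 3 days, STZ normoglycemic against control and diabetic against STZ normoglycemic at day 7, the 3 changes of the diabetic effect between days, and the 3 differences between control days. All were fitted in limma 3.58.1 under R 4.3.3, with 7 group means over the 21 arrays, moderated variances and Benjamini-Hochberg adjustment over the tested probes. The threshold was an adjusted p of 0.05. Differences are given in log2 with the standard error (SE) of the fit, and group means with the SD over 3 arrays. Other packages were data.table (version 1.17.8) and MASS 7.3.60.0.1.

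A set of 36 gene lists, covering retinal cell types, other tissues of the eye, metabolism and stress responses, was written before the data were examined, along with the comparisons, the alternatives and the rule for naming genes. Each list was tested with camera in limma with a preset correlation of 0.01 between genes, adjusted over the 36 lists. Camera compares a list with all other genes, on moderated statistics. Camera with an estimated correlation and fry were run as alternatives. Lists share members in 20 pairs, of which the largest overlap is 5 genes between the pigment epithelium and retinoid cycle lists. Under the naming rule, up to 10 genes per direction with the largest differences are named among probes past the threshold. Where fewer than 5 pass, the 5 higher and 5 lower genes with the smallest unadjusted p are given as values that did not pass. Up to 4 genes are named from each list past the threshold and at most 2 from each other list described. The genes Gfap, Fgf2, Vegfa, Cryab, Txnip, Icam1 and Aldoc are given in every comparison in which the probe can be measured. A probe well above background on no array of 1 group is given as a bound, and without a fold where the bound lies under 1 or both groups are so. Results of 2 genes that the rule names are left out of the text. Each gene is represented by 1 probe, and other probes of opposite sign are stated.

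The file headers show that the arrays were scanned in 8 runs on 12 slides. Scan 1 held 1 diabetic and 1 control array of day 7, and scan 2 held 1 of each of day 28. Scan 3 held 1 control and 1 STZ normoglycemic array of day 7 with 1 diabetic array of day 84. Scan 4 held 1 diabetic array of day 7 with 1 control array of day 84, and scan 5 held 1 array of each group of day 7. Scan 6 held 2 diabetic and 2 control arrays of day 28, scan 7 held 2 of each of day 84, and scan 8 held 1 STZ normoglycemic array. Arrays of the same scan correlated at a median r of 0.979 over 21 pairs and arrays of different scans at 0.898 over 189 pairs. Arrays of the same group in different scans correlated at 0.895. For this reason values with scan as a block, and values within scans, stand beside the main ones. Scan 8 held 1 array alone, so with scan as a fixed block that array carries no weight in any comparison. The array numbers follow the order of deposition. Diabetic and control arrays of the same number carry different title letters, while within a treatment a number stands for the same letter at each of the 3 days; the labels do not say what the letter marks. After group means were removed, all 3 pairs of the same letter at days 28 and 84 correlated over 0.1, in control retina (0.35 to 0.63) and in diabetic retina (0.48 to 0.71). The letter is therefore taken as a possible pairing of the arrays of these 2 days. Between scans 6 and 7, pairs of the same letter were at 0.38 and 0.35 in control and 0.48 and 0.51 in diabetic retina. Pairs of other letters there were about as high (0.41 and 0.37, and 0.43 and 0.60), so these correlations do not tell letter from scan.

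The arrays differ in signal, with 75th percentiles from 34.4 to 1387 intensity units and with 44.5 to 79.5% of probes well above background. The number of arrays limits the precision: the residual SD between arrays was 0.78 log2 at the median probe and 1.52 at the 90th percentile. The pipeline was tested on simulated data with this residual spread. At 3 arrays against 3, at day 28, it recovered 0 of 50 probes changed 2-fold, 17 of 50 changed 4-fold, 31 of 50 changed 8-fold and 35 of 50 changed 16-fold, with 8 false calls among 91. For the mean of 3 days it recovered 14, 28, 45 and 43 of 50 at those folds, with 8 false calls among 138. In the same simulation 3 of 3 lists of 15 genes shifted by 1 log2 were recovered, with 0 false calls. Errors were drawn independently for each gene and array, so correlation between genes and differences between scans were absent. False calls of the list tests under such structure were therefore not tested.

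Alternatives for the probe counts were normexp background correction with an offset of 50, quantile and cyclic loess normalization, no filter, a filter on all 21 arrays, slide, scan, extraction protocol and title letter as blocks, fits on only the groups compared, trend and robust variances, array weights, an adjusted p of 0.1, an unadjusted p of 0.05 with a 1.5-fold minimum, the deposited value table, and each array left out in turn. For lists, the mean of all probes of a gene, other normalizations and other tests were run. Scan and slide blocks for the lists and for the correlations, the title letter block for the lists, and fits without the array that stands apart, were chosen after seeing the data. So were exact permutation tests of the array labels on the mean of each list. Random regroupings of the arrays were counted for each comparison. The median log2 difference over all tested probes reached 0.29 in size under the main scaling, 0.08 under quantile normalization and 0.53 under normexp; differences are relative to the 75th percentile of each array.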

Results

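Retinal RNA of 63 rats was measured on 21 arrays, each a pool of 3 retinas from 3 animals. Diabetic rats (hyperglycemic after STZ) and buffer-injected controls were taken at days 7, 28 and 84, and a group of STZ-injected rats that stayed normoglycemic was taken at day 7, with 3 arrays in each of the 7 groups. The arrays carried 75th-percentile signals of 34.4 to 1387 intensity units, and 44.5 to 79.5% of their probes were well above background. The lowest signal, 34.4, was that of array 3 of the control group at day 7. Array 3 of the control group at day 84 stood apart: it correlated with the other 3 arrays of its slide at r = 0.902 to 0.903, while those correlated with one another at 0.989 to 0.991.

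The comparison of diabetic with control retina at day 7 asks what the retina's transcripts look like after 1 week of hyperglycemia. Crystallins, the structural proteins and chaperones of the lens that are also made in retinal neurons and glia, were higher in diabetic retina. All 13 measured members lay above the control mean, by a mean of 1.57 log2 (SD 0.29 over genes; camera adjusted p = 5.9e-09, and 0.659 with an estimated correlation between genes). Among them Cryaa differed by 1.92 ± 1.22 (SE, n = 3 arrays per group), Crybb2 by 1.85 ± 1.17, Crygb by 1.80 ± 0.98 and Cryge by 1.27 ± 0.82. Heat shock genes were higher by a mean of 0.24 (12 of 14 members; adjusted p = 0.0227, and 0.659 with an estimated correlation), with the mitochondrial chaperone Hspd1 at 0.40 ± 0.33, the constitutive chaperone Hspa8 at 0.43 ± 0.36 (1 of its 3 other probes of opposite sign), Dnaja1 at 0.29 ± 0.27 and Cryab at 1.08 ± 0.91. Genes of the unfolded protein and amino acid stress response were higher by 0.16 (15 of 18 members; adjusted p = 0.0371, and 0.976 with an estimated correlation), with the serine synthesis enzyme Psat1 at 0.73 ± 0.43, Dnajb9 at 0.49 ± 0.33, Slc3a2 at 0.31 ± 0.28 and Ddit3 at 0.29 ± 0.39. No member of these 3 lists passed when adjusted over the list alone.

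The crystallin difference varied with the arrays. It was 0.53 within scan 1 and 3.47 within scan 5, the scans that held both groups, and 1.64 with scan as a block (adjusted p = 1.1e-08, and 0.981 with an estimated correlation as well). Without array 3 of the control group, the array of lowest signal, it was 0.43 and no longer passed (adjusted p = 0.104), and without array 1 it was 2.42. Heat shock genes shifted by 0.18 with scan as a block (adjusted p = 0.154) and unfolded protein genes by 0.05 (adjusted p = 0.38). The heat shock list kept its call without Cryab, which is also a crystallin (0.18, adjusted p = 0.0416), and lost it in 5 of 6 fits that left out 1 array (0.13 without array 3 of the control group); the unfolded protein list lost it in 6 of 6 (0.25 without array 1 of the control group). Lens markers other than crystallins differed by 0.14 at day 7 (adjusted p = 0.758). Over all 21 arrays the mean of the crystallins followed the mean of these lens markers (Pearson r = 0.909, Spearman correlation 0.90, permutation p = 1e-05 for each, the smallest that 100000 permutations can give). This is 1 of 5 versions computed of this relation, with a Benjamini-Hochberg adjusted p of 1e-05 as well. The r was 0.855 without the 2 arrays farthest from the median lens score and 0.833 after scan means were removed (20 arrays).

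**Figure D1:**
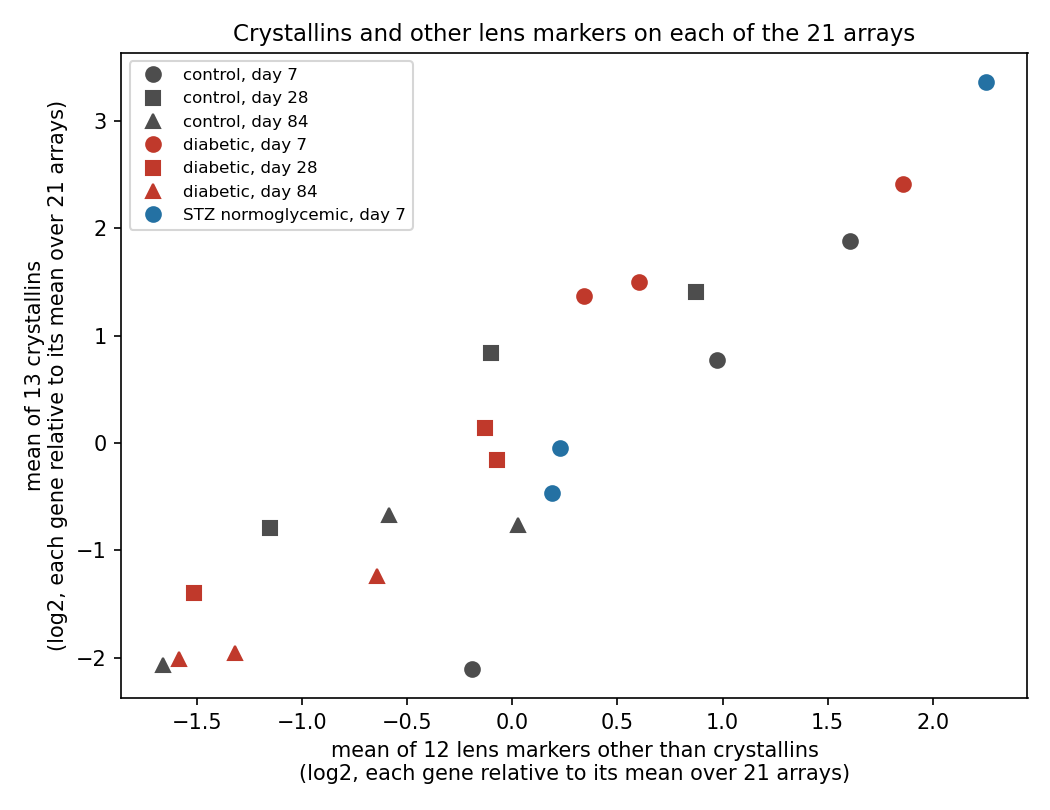
Mean log2 signal of 13 crystallins (vertical axis) against that of 12 other lens markers (horizontal axis), each gene relative to its mean over the arrays, with 1 point per array and shape and colour for day and group. The points rise together, with r = 0.909 over 21 arrays, and array 3 of the control group at day 7 is the point with a low crystallin mean at a lens score near 0.

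At day 7 no probe of 34588 passed in limma (smallest adjusted p 0.9999), 640 had an unadjusted p under 0.05 and 1729 would by chance. Of those 640, 615 were lower in diabetic retina. The genes with the smallest p, none of which passed, included as higher Cbll1 (2.86 ± 0.90 log2), Haus1 (1.13 ± 0.38), Baz1a (0.92 ± 0.33) and Mettl18 (0.71 ± 0.26). Lower values were those of Gbf1 (-1.98 ± 0.55), Mtrex (-1.23 ± 0.34), the proprotein convertase Pcsk5 (-1.15 ± 0.35), the cell cycle factor Foxm1 (-1.52 ± 0.47) and the ephrin receptor Epha8 (-2.05 ± 0.64). Other probes had the opposite sign for Cbll1 (2 of 2), Haus1 (1 of 1) and Mtrex (3 of 3). Groups of arrays did not overlap for 6.24% of probes, where chance gives 10%.

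At day 28, the comparison asks about 4 weeks of hyperglycemia. Markers of the retinal pigment epithelium and choroid, the pigmented layers behind the photoreceptors, fell. Of 13 measured members 12 were lower, by a mean of -0.87 log2 (camera adjusted p = 1.7e-22), and the list passed with an estimated correlation as well (adjusted p = 0.00532). Rgr, an opsin of the pigment epithelium and Muller glia, differed by -1.14 ± 0.40 (SE), from 2.66 ± 0.34 (SD, n = 3) in control to 1.52 ± 0.14 in diabetic retina. Lrat, which esterifies retinol for the visual cycle, differed by -1.16 ± 0.46, Rdh5 by -1.15 ± 0.52, and the melanosome gene Mlana by -0.97 ± 0.47; their arrays did not overlap between groups. The list's shift was -0.96 within scan 2 and -0.83 within scan 6. It passed with scan as a block (adjusted p = 2.1e-10), though not with that block and an estimated correlation together (adjusted p = 0.402), and it passed in 6 of 6 fits that left out 1 array.

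Retinoid cycle genes shifted by -0.40 at day 28 (15 of 18 lower; adjusted p = 5.1e-06, and 0.0395 with an estimated correlation). This list shares Rgr, Lrat, Rdh5, Rpe65 and Stra6 (-1.21 ± 0.61) with the pigment epithelium list, and without these 5 genes its shift was -0.12 (adjusted p = 0.715). Photoreceptor lists were lower by less. Rod genes shifted by -0.24 (15 of 20 lower; adjusted p = 0.00842, and 0.418 with an estimated correlation), with the rod phosphodiesterase subunits Pde6a at -0.38 ± 0.28 and Pde6b at -0.36 ± 0.33, and the guanylate cyclases Gucy2f at -1.61 ± 1.01 and Gucy2d at -0.50 ± 0.42. Cone genes shifted by -0.22 (10 of 12 lower; adjusted p = 0.027, and 0.418 with an estimated correlation), with cone transducin Gnat2 at -0.48 ± 0.30, the cone opsin Opn1mw at -0.48 ± 0.30, cone arrestin Arr3 at -0.33 ± 0.33 and the channel subunit Cngb3 at -0.59 ± 0.78. Within scans 2 and 6 the rod list shifted by -0.21 and -0.25 and the cone list by -0.08 and -0.29. The rod list passed with scan as a block (adjusted p = 0.0074, and 0.627 with an estimated correlation as well) and the cone list did not (adjusted p = 0.0611). Of the 6 fits that left out 1 array, the rod list passed in 2 and the cone list in 0, and the rod shift was -0.13 without array 1 of the control group or array 2 of the diabetic group and -0.36 without array 1 of the diabetic group.

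Crystallins were lower at day 28 (13 of 13 members, mean -0.96, adjusted p = 2.4e-06; 0.418 with an estimated correlation), by -1.56 within scan 2 and -0.65 within scan 6. The shift was -0.49 without array 3 of the diabetic group and -0.50 without array 1 of the control group, where the list did not pass (adjusted p = 0.0847 and 0.0875), and -1.59 without array 2 of the control group. Crygc differed by -2.31 ± 0.96, Crygb by -1.35 ± 0.98, Cryge by -1.29 ± 0.82 and Crygd by -1.15 ± 1.00. The other lens markers shifted by -0.44 (9 of 12 lower; adjusted p = 0.0794). Higher by small means were genes of extracellular matrix (0.10, 17 of 25 higher, adjusted p = 0.0135; 0.449 with an estimated correlation), among them Fn1 at 0.45 ± 0.29, Mmp14 at 0.35 ± 0.39, Lamb1 at 0.41 ± 0.49 and Lox at 0.24 ± 0.31 (its other probe -0.03). The p53 list was higher by 0.09 (14 of 19; adjusted p = 0.0272, and 0.168 with an estimated correlation), with Fas at 0.76 ± 0.60, Btg2 at 0.23 ± 0.33, Gadd45a at 0.24 ± 0.40 and Sesn1 at 0.17 ± 0.31. Immediate early genes were higher by 0.11 (12 of 19; adjusted p = 0.0321, and 0.717 with an estimated correlation), with Fos at 0.66 ± 0.41, Egr1 at 1.25 ± 0.82, Atf3 at 0.37 ± 0.53 and Fosl1 at -1.04 ± 0.68. The mean of each of these 3 lists turned below 0 without 1 of the arrays. Any of the 6 arrays moved the extracellular matrix shift (-0.09 to 0.42) and the immediate early shift (-0.20 to 0.44) by over 1.5 times, and arrays 1 and 2 of either group moved the p53 shift so (-0.01 to 0.17). The extracellular matrix and p53 lists passed with scan as a block (adjusted p = 0.0228 and 0.0295) and the immediate early list did not (adjusted p = 0.0611). None of the 3 passed with an estimated correlation as well (adjusted p = 0.627, 0.402 and 0.627). The extracellular matrix shift was -0.36 within scan 2 and 0.33 within scan 6. The p53 and immediate early lists share Btg2, without which neither passed (adjusted p = 0.0511 and 0.0671).

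No probe passed at day 28 in limma (smallest adjusted p 1, 42 with an unadjusted p under 0.05). With array weights 87 probes passed. These weights were estimated gene by gene and ranged from 0.145 to 10.5, since the default estimate gave no usable values with 3 arrays per group, and what the counts under them mean is uncertain. Named among the 87 were Rgr, Cryge, Rdh5, Crygc, Lgsn, Tap2, Lrat, RT1-N1, Opn1mw, Rorb, Fn1 and Bpifb4. The genes of smallest p in the unweighted fit were, as higher, the class I histocompatibility genes RT1-N1 (1.94 ± 0.70) and RT1-CE16 (0.88 ± 0.39), the cysteine synthesis enzyme Cth (1.28 ± 0.61), Bpifb4 (0.76 ± 0.36) and Muc20, which was well above background on none of these 6 arrays and is given no difference. As lower they were the lens gene Lgsn (-2.57 ± 0.84), Rgr, and the cell division genes Espl1 (-1.74 ± 0.57), Cep295 (-1.33 ± 0.44) and Kif20b (-0.99 ± 0.39). RT1-CE16 stood at 2.19 ± 0.08 (SD, n = 3) in diabetic and 1.32 ± 0.20 in control retina. Groups did not overlap for 4.2% of probes, where chance gives 10%.

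**Figure D2:**
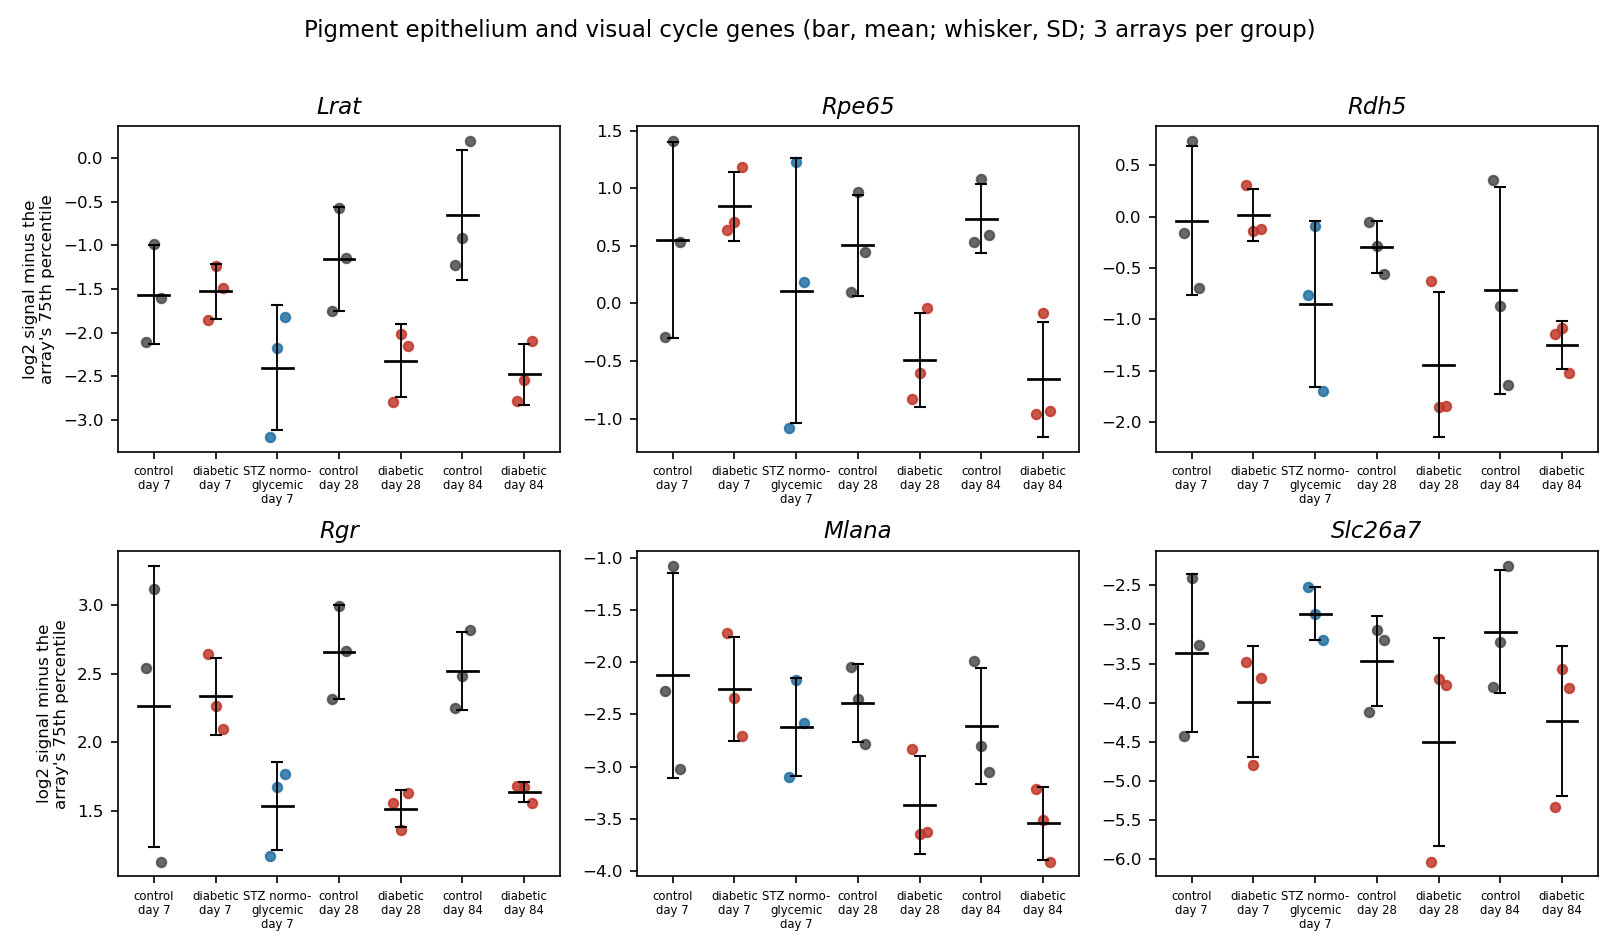
Log2 signal relative to the array's 75th percentile (vertical axis) of 6 pigment epithelium genes in the 7 groups (horizontal axis), with 1 point per array, bars at the mean and whiskers of 1 SD (n = 3). At day 28 the diabetic arrays lie below the control arrays without overlap for Lrat, Rpe65, Rdh5, Rgr and Mlana, and at day 84 for Lrat, Rpe65, Rgr and Mlana.

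At day 84, after 12 weeks, pigment epithelium markers were again lower (11 of 13, mean -0.76; adjusted p = 1.4e-06, and 0.519 with an estimated correlation). Lrat differed by -1.83 ± 0.46, Rpe65, the isomerase of the visual cycle, by -1.40 ± 0.52, Mlana by -0.93 ± 0.47 and Rgr by -0.88 ± 0.40. Of the members 1 passed when adjusted over the list alone. The shift was -0.55 within scan 7 and -0.76 with scan as a block (adjusted p = 0.00133, and 0.862 with an estimated correlation as well). The list passed in 6 of 6 fits that left out 1 array. Oxidative stress genes did not pass at day 84 (mean 0.42, 20 of 23 higher, adjusted p = 0.0719) and passed with scan as a block (0.52, adjusted p = 0.0153; 0.862 with an estimated correlation as well). That blocked shift was 0.13 (adjusted p = 0.0398) without array 3 of the control group, the array that stands apart; metallothionein Mt1 was at 1.82 ± 0.83 and the quinone reductase Nqo1 at 0.79 ± 0.44. With that block the mitochondrial respiratory chain (0.41, adjusted p = 0.0153) and the unfolded protein response (0.39, adjusted p = 0.0498) also passed, with an adjusted p of 0.862 for both with an estimated correlation as well; without the block they shifted by 0.29 and 0.27. Without array 3 of the control group their blocked shifts were 0.17 (adjusted p = 0.00209) and 0.06 (adjusted p = 0.469). Antigen processing and interferon genes Tap2 and Irf1 were at 1.34 ± 0.50 and 1.24 ± 0.60, in a list that did not pass.

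No probe passed at day 84 in limma (smallest adjusted p 0.9999, 538 with an unadjusted p under 0.05). Array weights gave 92 probes, including Crygc, Cldn16, Lrat, Or5m9 and Bpifb4, and scan as a block without the array that stands apart gave 3. The genes with the smallest p were, as higher, Ell3 (2.28 ± 0.57), Fank1 (1.82 ± 0.51), Prrx2 (1.37 ± 0.41), Bpifb4 (1.26 ± 0.36) and the secreted ribonuclease Rnase4 (1.5 ± 0.44). As lower they were the laminin chain Lamb3 (-2.31 ± 0.58), Boc (-2.72 ± 0.83), Lrat, the olfactory receptor Or5m9 and the tight junction gene Cldn16. The last pair were not well above background on any diabetic array, and at the background of those arrays Cldn16 was at least 8.1-fold and Or5m9 at least 1.41-fold lower. Groups did not overlap for 5.7% of probes, where chance gives 10%.

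Over the mean of 3 days, pigment epithelium markers were lower (13 of 13, mean -0.53; adjusted p = 5.9e-08, and 0.301 with an estimated correlation), with Lrat at -0.98 ± 0.27, Slc26a7 at -0.94 ± 0.39, Mlana at -0.68 ± 0.27 and Rgr at -0.65 ± 0.23. Oxidative stress genes were higher by 0.18 (20 of 23; adjusted p = 0.00977, and 0.915 with an estimated correlation), with the glutathione transferase Gstm1 at 0.37 ± 0.21, Nqo1 at 0.41 ± 0.25, Mt1 at 0.72 ± 0.48 and catalase Cat at 0.26 ± 0.25. Both passed with scan as a block (adjusted p = 2.1e-04 and 0.00361). The oxidative stress call was lost without array 1 of the diabetic group at day 7 (0.12), array 3 of the control group at day 7 (0.11), or array 1 of the control group at day 84 (0.25), and without array 3 of the control group at day 84 the shift was 0.07 (adjusted p = 0.0364). With scan as a block and an estimated correlation together neither list passed (adjusted p = 0.966 for both). Exact permutation of the array labels within each day on the mean of each list, chosen after seeing the data, gave p = 0.0255 for pigment epithelium markers, which did not pass over 36 lists (adjusted p = 0.918), nor did any other list. The labels of each day were permuted independently, so a possible pairing of arrays between days by title letter was not kept. No probe passed in limma (smallest adjusted p 0.9999, 723 with an unadjusted p under 0.05, 650 of them lower). Array weights gave 178 probes, among them Lalba, Bpifb4, Rgr, Chi3l1, Mlana, Lrat, Rnase4, Clock and Tap2, and scan as a random block gave 1. The smallest p belonged to Bpifb4 (0.82 ± 0.21), Rnase4 (0.97 ± 0.25), the dynein light chain Dynll2 (0.76 ± 0.25), the protease inhibitor Serpine2 (0.55 ± 0.19) and the secreted glycoprotein Chi3l1 (0.60 ± 0.21) as higher, each above 0 at all 3 days. As lower they were Lalba (at least 1.38-fold at background), Lrat, Kif20b (-0.80 ± 0.23), the GABA receptor subunit Gabrg3 (-0.89 ± 0.26) and the netrin receptor Unc5d (-1.32 ± 0.38). Lalba was well above background on 0 of 9 diabetic and 6 of 9 control arrays.

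**Figure D3:**
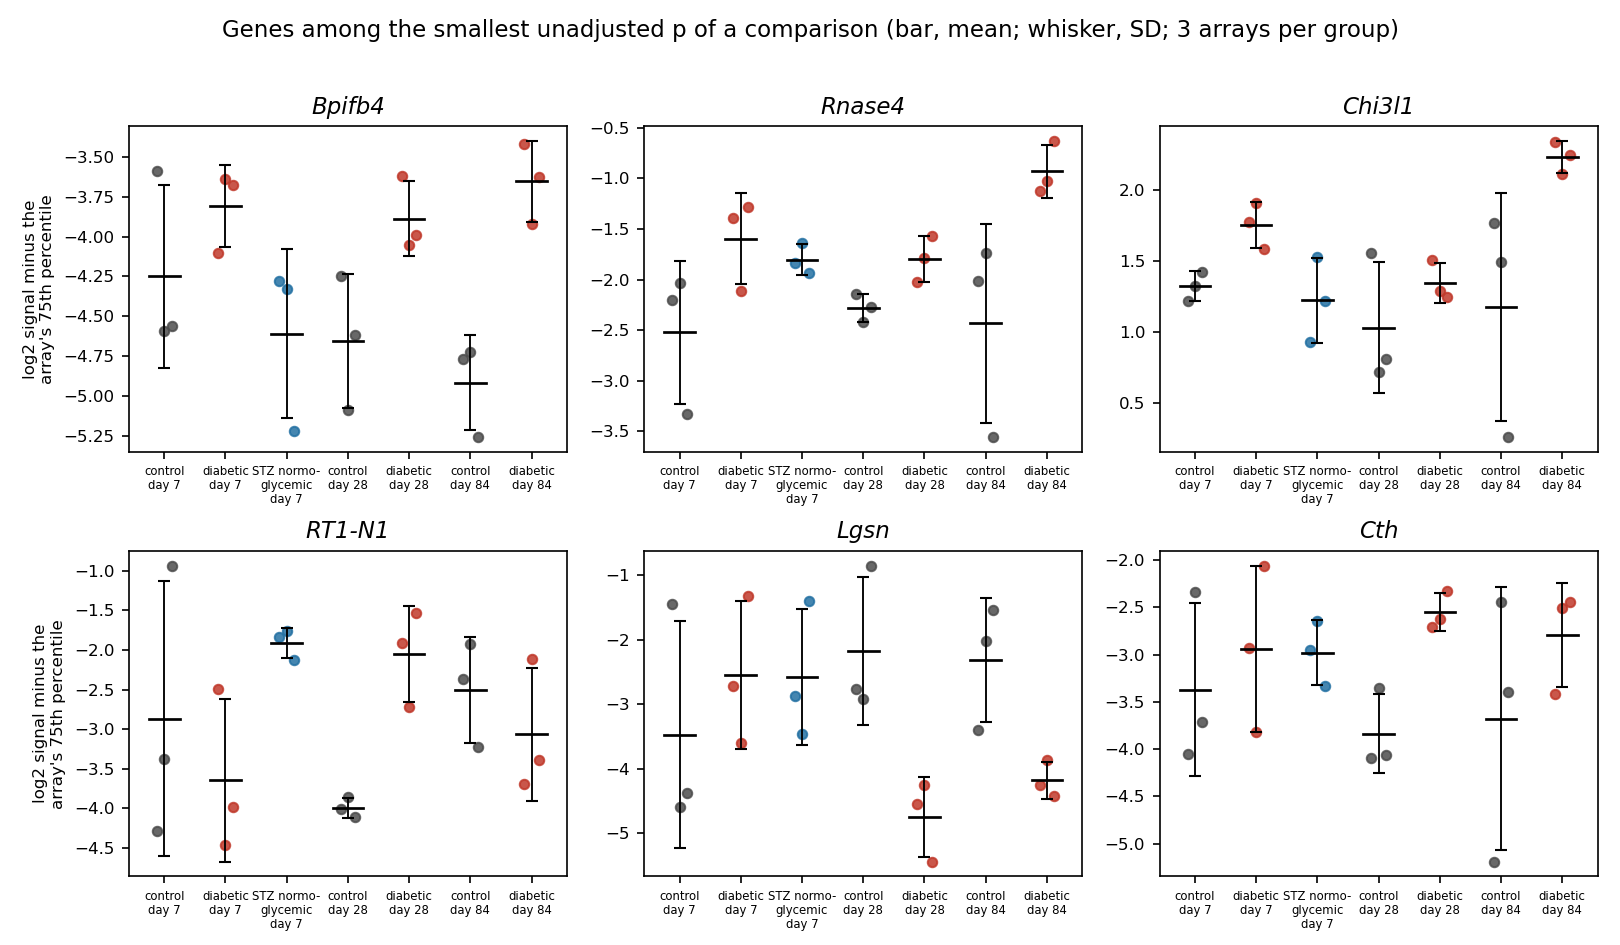
Log2 signal relative to the array's 75th percentile (vertical axis) of 6 genes among those of smallest unadjusted p, in the 7 groups (horizontal axis), with 1 point per array, bars at the mean and whiskers of 1 SD (n = 3). None of these genes passed; Bpifb4 differed by 0.44, 0.76 and 1.26 log2 at days 7, 28 and 84.

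The remaining lists did not pass over the mean of 3 days. Their shifts were 0.11 for the unfolded protein response (adjusted p = 0.0825), 0.14 for heat shock (0.112), 0.10 for fasting and fatty acid oxidation (0.404), 0.10 for the respiratory chain (0.404), 0.07 for glycolysis (0.404) and 0.04 for the p53 response (0.441). The adjusted p was 0.508 for glucocorticoid response (0.04), and 0.509 for reactive gliosis (0.05), lens markers (-0.25), inflammatory mediators (-0.14), extracellular matrix (0.04), interferon response (0.07) and complement (0.05). It was 0.547 for synaptic genes (-0.12), 0.56 for Muller glia and astrocytes (-0.05), 0.687 for skeletal muscle and ocular surface (-0.02) and apoptosis regulators (0.02), 0.695 for cone genes (-0.15) and 0.798 for vascular cells (0.03). It was 0.806 or 0.807 for the retinoid cycle (-0.10), cholesterol synthesis (-0.08), immediate early genes (0.00), amacrine (0.00), horizontal (0.01) and bipolar cells (0.03), insulin signalling (-0.05), rod genes (-0.03) and clock genes (-0.06). It was 0.824 for the polyol and glycation pathways (0.00) and hypoxia and angiogenic factors (-0.06), 0.901 for crystallins (0.02), microglia (-0.07) and blood (-0.17), and 0.976 for ganglion cells (-0.10). Of all 432 list tests, mean, median and tested direction differed in sign in 151, none of them among the 29 past the threshold.

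**Figure D4:**
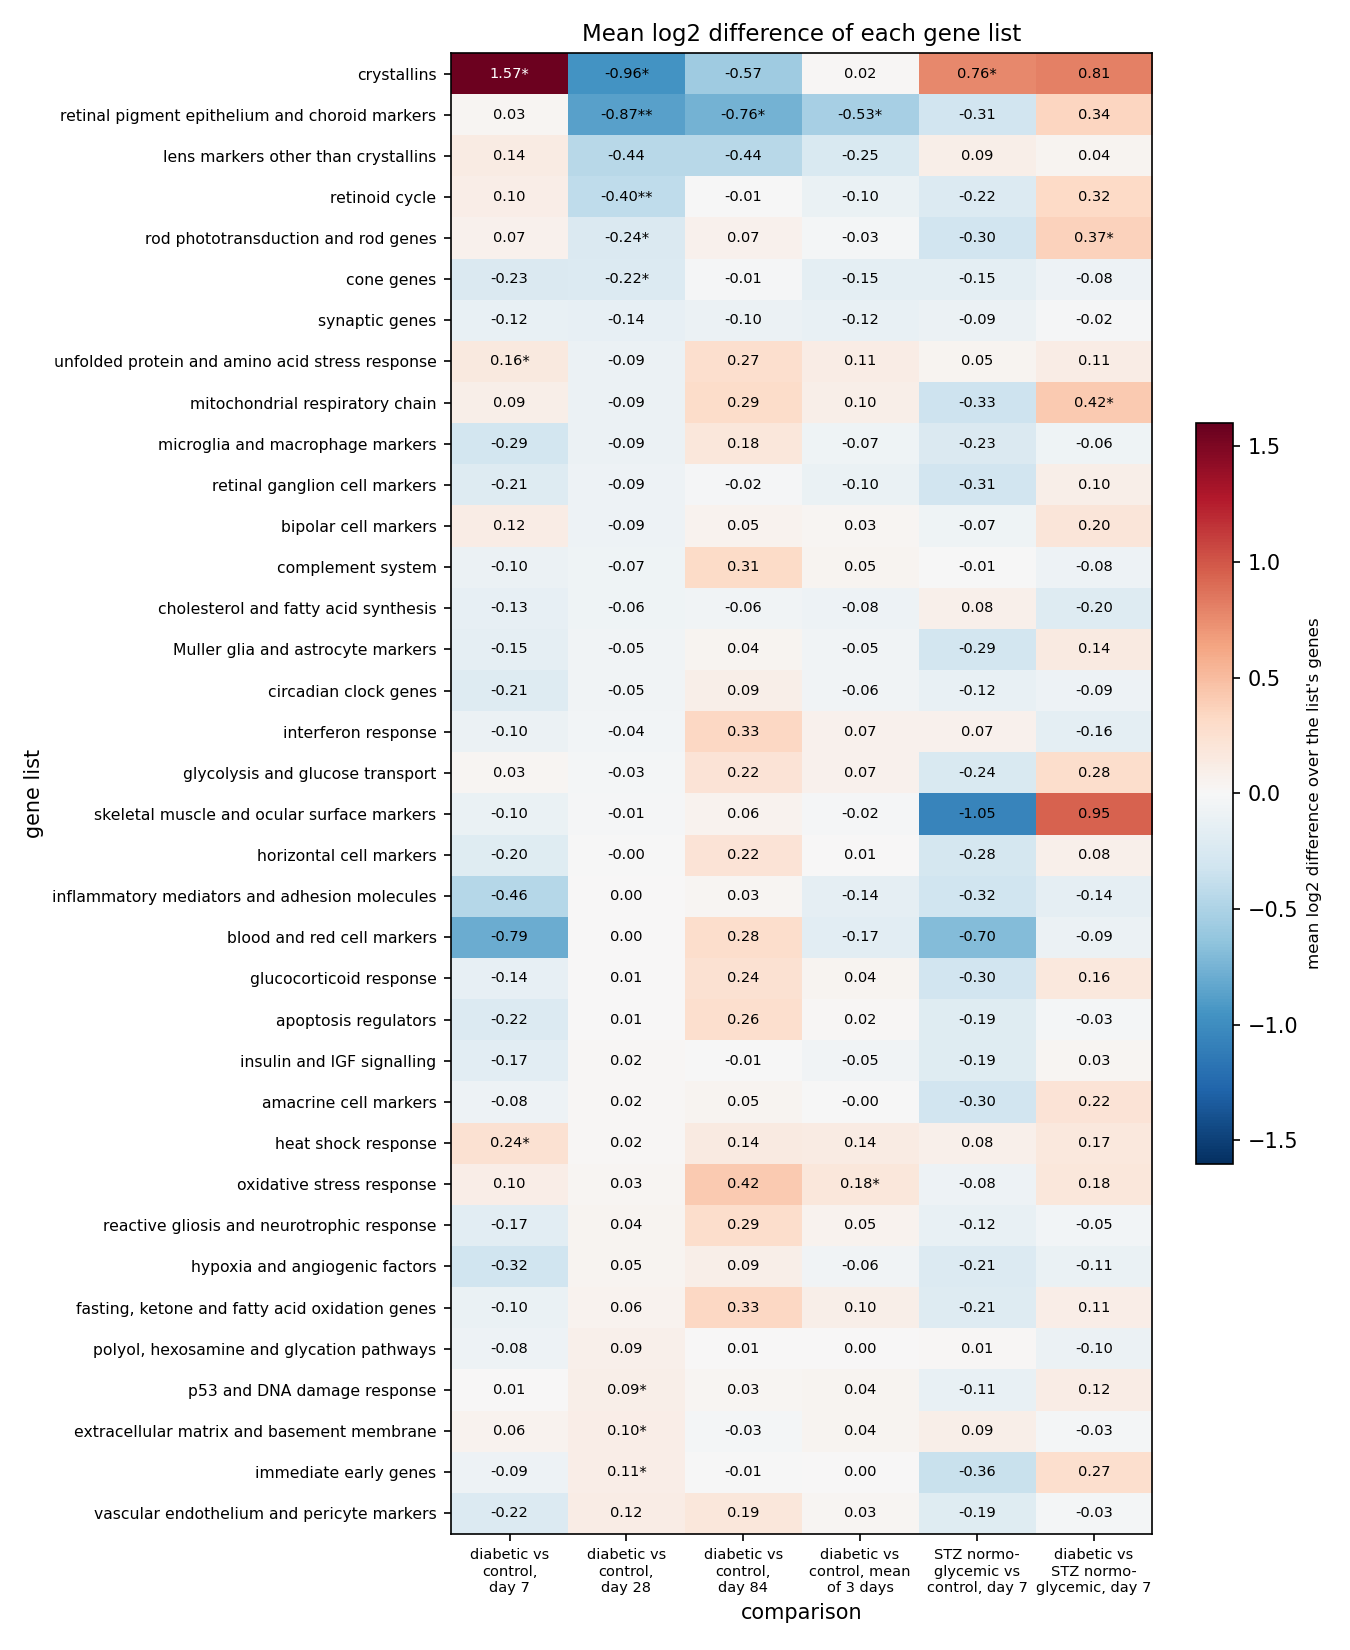
Mean log2 difference of each of 36 gene lists (rows) in the 6 comparisons of treatment groups (columns), coloured from blue (lower) to red (higher); * marks a camera adjusted p under 0.05 with the preset correlation and ** also with an estimated one. Pigment epithelium markers at day 28 (-0.87) and the retinoid cycle (-0.40) carry **.

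Of the genes often measured in diabetic retina and fixed in advance, the 7 given here did not pass in limma without array weights in any of the 12 comparisons (smallest adjusted p 0.291, Fgf2 in control retina, day 84 against day 7). Array weights brought 3 of them past the threshold, only between control days, given below. The glial filament Gfap differed between diabetic and control retina by -0.59 ± 0.75, -0.42 ± 0.75 and 0.32 ± 0.75 log2 at days 7, 28 and 84 (1.40 within scan 7), Fgf2 by -0.92 ± 0.67 at day 7 and -0.36 ± 0.67 at day 84 (its other probe 0.23 at day 84), and Vegfa by -0.02 ± 0.69, -0.22 ± 0.69 and -0.01 ± 0.69 (its other probe 0.15 and 0.33 at days 7 and 84). Cryab differed by 1.08 ± 0.91, -0.15 ± 0.91 and -0.11 ± 0.91, and the thioredoxin inhibitor Txnip by 0.86 ± 1.31 and 0.44 ± 1.31 at days 28 and 84. Fgf2 was not well above background on any array of either group at day 28, and was so on 1 of 3 in each at days 7 and 84. Txnip was not well above background on any control array at day 7. Differences that rest on such a group are given for these 2 genes only as bounds, or not at all. The leukocyte adhesion molecule Icam1 differed by -0.03 ± 0.59, 0.44 ± 0.59 and 0.90 ± 0.59 (1.13 within scan 7) and Aldoc by 0.11 ± 0.48, 0.10 ± 0.48 and 0.71 ± 0.48. Over the mean of 3 days the values were -0.23 ± 0.43 for Gfap, -0.08 ± 0.40 for Vegfa, 0.27 ± 0.53 for Cryab, 0.44 ± 0.34 for Icam1 and 0.31 ± 0.28 for Aldoc.

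**Figure D5:**
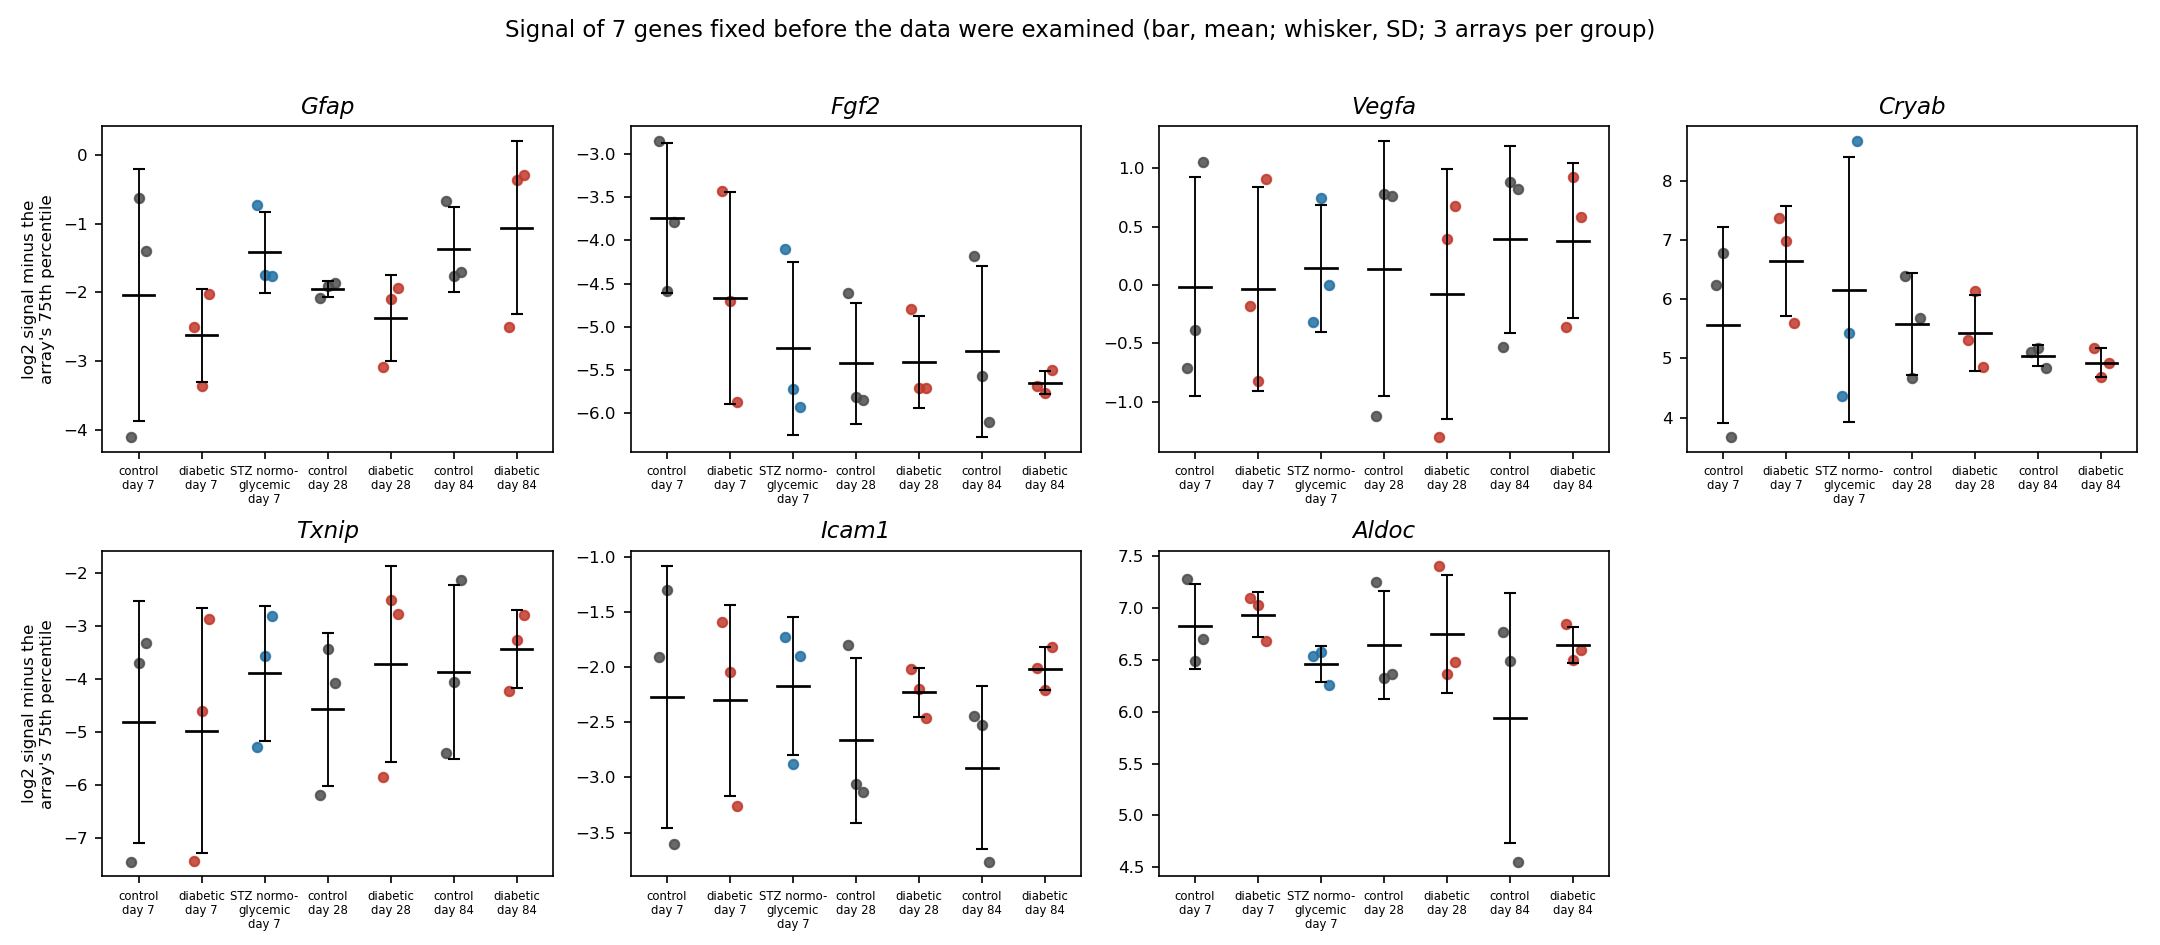
Log2 signal relative to the array's 75th percentile (vertical axis) of 7 genes fixed in advance, in the 7 groups (horizontal axis), with 1 point per array, bars at the mean and whiskers of 1 SD (n = 3). At day 84 the diabetic arrays of Icam1 lie above the control arrays (difference 0.90 ± 0.59), and the groups overlap for the other 6 genes.

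The STZ-injected rats without hyperglycemia address what the toxin itself leaves in the retina at day 7. Against control, crystallins were higher (13 of 13, mean 0.76; adjusted p = 0.016, and 0.96 with an estimated correlation), with Crygb at 0.99 ± 0.98, Cryge at 0.87 ± 0.82, Crybb2 at 0.92 ± 1.17 and Crybb1 at 0.87 ± 1.1. The shift was -1.24 within scan 3 and 2.05 within scan 5. It was 0.13 with scan as a block (adjusted p = 0.996), which gives array 3 of the STZ normoglycemic group no weight. It was -0.44 without array 3 of the STZ normoglycemic group and -0.38 without array 3 of the control group, where the list did not pass, and 1.26, 1.47 and 1.61 without array 2 or 1 of the STZ normoglycemic group or array 1 of the control group. Skeletal muscle and ocular surface markers shifted by -1.05 (13 of 14 lower) and did not pass (adjusted p = 0.419), and with scan as a block by -1.15 (adjusted p = 0.00101; 0.999 with an estimated correlation). No probe passed in limma (smallest adjusted p 0.899, 876 with an unadjusted p under 0.05). The smallest p belonged, as higher, to the kinase Sik1 (0.90 ± 0.29), Baz1a (1.05 ± 0.33), Cdv3l1 (1.18 ± 0.40), the neuroserpin gene Serpini1 (3.26 ± 1.11; 7.53 within scan 3 and 0.35 within scan 5) and the angiopoietin receptor Tek (at least 1.52-fold; its other probe -0.51 log2). As lower they were Dhx9 (at least 2.57-fold), Muc4 (at least 2.1-fold), Wfdc18 (at least 1.06-fold), Samd13 (at least 1.59-fold) and Paqr5 (at least 3.1-fold), bounds taken at the background of arrays that were not well above it. Groups did not overlap for 4.44% of probes, where chance gives 10%. Gfap was at 0.62 ± 0.75, Vegfa at 0.16 ± 0.69 (its other probe -0.53), Cryab at 0.60 ± 0.91, Icam1 at 0.10 ± 0.59 and Aldoc at -0.37 ± 0.48. Fgf2, well above background on only 1 of these control arrays, is given no fold.

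Diabetic against STZ normoglycemic retina at day 7 compares STZ-injected rats with and without hyperglycemia. These groups were sorted by blood glucose after the injection, not assigned, so hyperglycemia is not fully separated from the response to the toxin. Respiratory chain genes were higher by 0.42 (24 of 25; adjusted p = 0.0106, and 0.876 with an estimated correlation), with Cox8a at 0.83 ± 0.68, Ndufv2 at 0.56 ± 0.42, Cox7a2 at 0.44 ± 0.37 and the ATP synthase subunit Atp5f1b at 0.35 ± 0.29. Rod genes were higher by 0.37 (17 of 20; adjusted p = 0.019, and 0.876 with an estimated correlation), with the rod transcription factor Nrl at 1.3 ± 0.49, Rom1 at 1.37 ± 0.80, recoverin, Rcvrn, at 0.55 ± 0.34 and Cnga1 at 0.52 ± 0.34. With scan as a block the shifts were 0.02 (adjusted p = 0.123) and 0.09 (adjusted p = 0.00388), and within scan 5, the scan that held both groups, 0.16 and 0.14. With that block and an estimated correlation together neither list passed (adjusted p = 0.989 and 0.574). The block gives array 3 of the STZ normoglycemic group, alone in scan 8, no weight. Both calls were lost without array 3 of the diabetic group or array 1 of the STZ normoglycemic group, and the respiratory chain call also without array 2 of the diabetic group; the rod shift was 0.24 without array 3 of the STZ normoglycemic group. Quantile normalization gave 0.02 and 0.01 (adjusted p = 0.874 and 0.966). Muscle and ocular surface markers shifted by 0.95 (11 of 14 higher; adjusted p = 0.1, and 1.6e-08 with a shift of 1.36 with scan as a block). With that block and an estimated correlation together they did not pass (adjusted p = 0.544).

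No probe passed between diabetic and STZ normoglycemic retina in limma (smallest adjusted p 0.986, 368 with an unadjusted p under 0.05). The smallest p belonged to the muscle genes Cox6a2 (2.88 ± 0.95) and Tnni2 (2.72 ± 0.95), Dynll2 (1.32 ± 0.44), Haus1 (1.17 ± 0.38) and the growth factor Epgn as higher. Epgn was well above background on 1 of the 6 arrays and is given no fold. As lower they were the basement membrane genes Nid1 (-2.45 ± 0.74), Pxdn (-2.75 ± 0.88) and P3h2 (-1.43 ± 0.47), with Sall1 (-1.39 ± 0.41) and Cpm (at least 1.8-fold). Groups did not overlap for 6.47% of probes, where chance gives 10%. Gfap was at -1.21 ± 0.75, Vegfa at -0.18 ± 0.69 (its other probe 0.68), Cryab at 0.49 ± 0.91, Txnip at -1.08 ± 1.31 (1.09 with scan as a block), Icam1 at -0.13 ± 0.59 and Aldoc at 0.48 ± 0.48. The effects of diabetes and of STZ without diabetes, both against the same 3 control arrays, correlated across 34588 probes at r = 0.597 (Spearman 0.554); genes are not independent replicates. Simulated groups without any difference that share controls gave r = 0.499 on average (0.487 to 0.513 in 100 simulations), and 47 of 100 regroupings of the real arrays gave an r as high. The covariance was 0.304, against 0.322 in the simulations. Both lists of calls were empty, so their overlap was 0.

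The diabetic effect was compared between days as a difference of differences. From day 7 to day 28 it changed for crystallins (mean -2.53, 13 of 13 members; adjusted p = 7.9e-16), pigment epithelium markers (-0.90, 12 of 13; 1.8e-09), the retinoid cycle (-0.51, 16 of 18; 2.3e-05), rod genes (-0.30, 16 of 20; 0.00251), the unfolded protein response (-0.26, 14 of 18; 0.00984) and the respiratory chain (-0.19, 23 of 25; 0.0421), all lower, and for blood and red cell markers (0.79, 10 of 11; 0.00984) and inflammatory mediators (0.46, 14 of 17; 0.0124), both higher. None of the 8 lists passed with an estimated correlation (adjusted p = 0.0968 for pigment epithelium and the retinoid cycle, 0.1 for crystallins, 0.302 for rods, 0.629 for the unfolded protein response and blood, 0.738 for inflammatory mediators and 0.928 for the respiratory chain). Crygc changed by -3.75 ± 1.36, Crygb by -3.15 ± 1.39, Cryge by -2.56 ± 1.17 and Crygd by -2.58 ± 1.42. Rgr changed by -1.21 ± 0.57, Lrat by -1.20 ± 0.66, Stra6 by -1.55 ± 0.87 and Rpe65 by -1.29 ± 0.74. The rod genes Pde6a, Pde6b, Gucy2d and Cnga1 changed by -0.73 ± 0.40, -0.50 ± 0.47, -0.62 ± 0.59 and -0.50 ± 0.47. The neutrophil gene S100a9 was at 1.99 ± 1.1, the platelet gene Pf4 at 0.93 ± 1.09, the red cell gene Alas2 at 0.73 ± 1.33, and the receptor Tlr2 and the cytokine Il18 at 1.46 ± 0.69 and 0.47 ± 0.56. S100a8, Il1b and Tlr4 were not well above background on any array of at least 1 of the groups compared and are given no change. Psat1 was at -0.92 ± 0.61, Dnajb9 at -0.60 ± 0.47, Pdia4 at -0.77 ± 0.67 and Hsp90b1 at -0.46 ± 0.42, and the respiratory chain genes Cycs, Uqcrc2, Ndufs1 and Ndufa9 at -0.50 ± 0.39, -0.37 ± 0.40, -0.53 ± 0.59 and -0.37 ± 0.45. With scan as a block the unfolded protein response (-0.14, adjusted p = 0.149) and the respiratory chain (-0.07, adjusted p = 0.311) did not pass, and with an estimated correlation as well none of the 8 did.

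Single arrays moved these changes. Without array 3 of the control group at day 7, the array of lowest signal, crystallins were at -1.38 and the retinoid cycle at -0.30, and both passed. Without the 5 genes it shares with the pigment epithelium list, the retinoid cycle was at -0.20 on all arrays and did not pass (adjusted p = 0.18). Rod genes were at -0.18 without array 2 of the control group at day 7 and did not pass (adjusted p = 0.236), and at -0.19 and -0.20, past the threshold, without array 1 of the control or array 2 of the diabetic group at day 28. Blood and red cell markers lost their call without array 1 of the diabetic group at day 28 (0.26), array 3 of the diabetic group at day 7 (0.46), array 3 of the control group at day 28 (0.46) or array 1 of the control group at day 7 (0.73), and were at 1.26 and 1.36 without array 1 of the diabetic group at day 7 or array 1 of the control group at day 28. Inflammatory mediators lost theirs without array 1 of the diabetic group at day 28 (0.19), array 3 (0.19) or 1 (0.62) of the diabetic group at day 7, array 2 of the control group at day 7 (0.20), or array 2 (0.29) or 3 (0.32) of the control group at day 28, and were at 0.77 without array 1 of the latter. The unfolded protein response lost its call without array 1 of either group at day 28 or array 2 of the control group at day 7. The respiratory chain lost its call in 7 of 12 such fits (-0.52 to 0.09, over 1.5 times larger or smaller, or turned, in 9). Quantile normalization ended the calls of rod genes (-0.28), blood (0.33), inflammatory mediators (0.15), the unfolded protein response (-0.16) and the respiratory chain (-0.04), and normexp that of blood (0.22); pigment epithelium markers were at -0.57 with normexp.

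From day 7 to day 84 the diabetic effect changed for crystallins (-2.14, 13 of 13; adjusted p = 2.6e-10), pigment epithelium markers (-0.79, 11 of 13; 4.9e-07) and blood and red cell markers (1.07, 9 of 11; 0.0154). With an estimated correlation the adjusted p was 0.479, 0.479 and 0.972. Crygc changed by -3.99 ± 1.36, Crygb by -3.53 ± 1.39, Cryba1 by -3.24 ± 1.73 and Cryaa by -2.24 ± 1.73, Lrat by -1.87 ± 0.66, Rpe65 by -1.69 ± 0.74, Rgr by -0.95 ± 0.57 and Tyrp1 by -1.23 ± 0.83. The blood genes S100a9, Alas2 and Slc4a1 were at 2.69 ± 1.1, 2.31 ± 1.33 and 1.77 ± 1.57. With scan as a block the blood list did not pass (1.20, adjusted p = 0.154). Without array 3 of the control group at day 7, crystallins were at -0.99 and pigment epithelium markers at -0.49 (adjusted p = 0.00719 for both), and the latter were at -1.23 without array 2. The blood list was at 0.61 and 1.70 without array 3 or 1 of the control group at day 84, where it passed, and at 0.25 with normexp (adjusted p = 0.564) and 0.71 with quantile normalization (adjusted p = 0.132); it lost its call in 5 of 12 fits that left out 1 array: without array 3 of either diabetic group, array 1 or 3 of the control group at day 7 or array 2 of that at day 84. From day 28 to day 84 no list passed. No probe passed in limma in any of these 3 comparisons, with 127, 205 and 84 at an unadjusted p under 0.05 (smallest adjusted p 1 in each). From day 7 to day 28 and from day 7 to day 84, in that order, the diabetic effect changed by 0.17 ± 1.06 and 0.90 ± 1.06 for Gfap, -0.20 ± 0.97 and 0.01 ± 0.97 for Vegfa, -1.24 ± 1.29 and -1.20 ± 1.29 for Cryab, 0.46 ± 0.83 and 0.92 ± 0.83 for Icam1, and -0.01 ± 0.68 and 0.59 ± 0.68 for Aldoc; from day 7 to day 84 that of Fgf2 changed by 0.56 ± 0.94. From day 28 to day 84 the values were 0.74 ± 1.06 for Gfap, 0.21 ± 0.97 for Vegfa, 0.04 ± 1.29 for Cryab, -0.42 ± 1.85 for Txnip, 0.46 ± 0.83 for Icam1 and 0.60 ± 0.68 for Aldoc.

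Across the 34588 probes, the diabetic effects of days 7 and 28 correlated at r = 0.209 (Spearman 0.106), those of days 7 and 84 at 0.399 (Spearman 0.338) and those of days 28 and 84 at 0.179 (Spearman 0.131). The signs were the same for 51.0, 60.1 and 53.1% of probes. Of 100 regroupings of the arrays within days, 42, 11 and 45 gave an r as large.

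Control retinas were compared between days as the course of age without treatment. From day 28 to day 84 crystallins were lower (-1.65, 13 of 13; adjusted p = 1.4e-05, and 0.946 with an estimated correlation), with Crygd at -3.49 ± 1.00, Crygc at -2.68 ± 0.96, Cryge at -2.29 ± 0.82 and Crygb at -1.73 ± 0.98. Without array 1 of the control group at day 84 the shift was -1.85 and did not pass (adjusted p = 0.138). The respiratory chain did not pass (-0.38, 22 of 25 lower; adjusted p = 0.064). It passed with title letter as a block (adjusted p = 0.0172, and 0.959 with an estimated correlation as well). The other control comparisons gave 0 lists. No probe passed in limma: the smallest adjusted p was 0.262 for day 28 against day 7 (4297 with an unadjusted p under 0.05), 0.253 for day 84 against day 7 (5708) and 0.9997 for day 84 against day 28 (331). Array weights gave 17252, 12252 and 106 probes. For day 28 against day 7 these included Fgf2, Icam1 (-1.44, adjusted p = 0.00339) and Vegfa (0.97, adjusted p = 0.0445). For day 84 against day 7 they included Fgf2 (-1.16, adjusted p = 0.0368), and for day 84 against day 28 Cryge (-1.86) and Crygd (-2.79). No scan held control arrays of 2 of these days, so age is not separated from scan; only day 84 against day 7 can be fitted with scan as a block (2705 probes with an unadjusted p under 0.05, none passing). For day 28 against day 7, Fgf2 was well above background on only 1 array of day 7 and none of day 28, and is given no fold. Gfap was at 0.09 ± 0.75, Vegfa at 0.15 ± 0.69 (its other probe -0.88), Cryab at 0.02 ± 0.91, Icam1 at -0.39 ± 0.59 and Aldoc at -0.18 ± 0.48. For day 84 against day 7, Gfap was at 0.67 ± 0.75, Fgf2 at -1.54 ± 0.67, Vegfa at 0.40 ± 0.69 (its other probe -1.55), Cryab at -0.52 ± 0.91, Icam1 at -0.64 ± 0.59 and Aldoc at -0.89 ± 0.48. For day 84 against day 28, the values were 0.58 ± 0.75 for Gfap, 0.25 ± 0.69 for Vegfa (its other probe -0.67), -0.54 ± 0.91 for Cryab, 0.71 ± 1.31 for Txnip, -0.25 ± 0.59 for Icam1 and -0.71 ± 0.48 for Aldoc.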

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

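The 6 tests of pigment epithelium, crystallin and array patterns, the intervals with scan as a block and over title letter pairs, the adjustment of shares of splits, and the exact permutation tests of the lists, were chosen after the results were seen; the counts of regroupings were fixed before.

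A difference between days in the effect of diabetes singled out 11 list results, each by a test of the difference itself. From day 7 to day 28 these were crystallins (-2.53), pigment epithelium and choroid markers (-0.90), the retinoid cycle (-0.51; -0.20 and adjusted p = 0.18 without the 5 genes it shares with the pigment epithelium list), rod genes (-0.30), the unfolded protein response (-0.26), blood and red cell markers (0.79), inflammatory mediators (0.46) and the respiratory chain (-0.19). From day 7 to day 84 they were crystallins (-2.14), pigment epithelium and choroid markers (-0.79) and blood and red cell markers (1.07). Their adjusted p with the preset correlation ranged from 7.9e-16 to 0.0421, and with an estimated correlation from 0.0968 to 0.972. Exact permutation of the array labels gave no list an adjusted p under 0.05 in these comparisons (smallest unadjusted p 0.07 and 0.11, over 400 labellings). Since 400 labellings cannot go under 0.005, 1 list alone could not have passed over 36 lists.

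Pigment epithelium and choroid markers were lower in diabetic than in control retina at days 28 and 84. Their list mean per array was -0.62 ± 0.06 (SD, n = 3) in diabetic and 0.25 ± 0.26 in control retina at day 28, -0.61 ± 0.14 and 0.15 ± 0.41 at day 84, and 0.40 ± 0.32 and 0.37 ± 0.78 at day 7. At day 28 scans 2 and 6 each held as many diabetic as control arrays. That balance makes the shift (-0.87) the same with and without scan as a block, so their equality tests nothing. An offset common to all arrays of a scan would cancel in it on that day. At day 84 the shift was -0.76 with and without the block. Scans 3 and 4 each held a day 84 array of only 1 group, so scan is less well separated there. The spread between arrays leaves the size of the shift uncertain. Within the scans that held both groups the shift nearest to 0 was -0.55. Over the arrays with scan as a block the list mean shifted by -0.81 for the mean of days 28 and 84 (95% interval -1.56 to -0.07), with the 2 days taken as independent, and the interval of each day alone held 0 (-1.88 to 0.13 and -1.87 to 0.35). With each pair of arrays of 1 title letter taken as a unit, within scans 6 and 7, the shift was -0.69 and its interval held 0 (-1.84 to 0.46, 2 pairs in each group). Different amounts of pigment epithelium in the dissected tissue may account for the pattern. Member genes also varied together within groups (mean correlation 0.278 after group means were removed, median 0.042 for 1000 random lists matched on signal, 19 of them as high). Genes that change together within the cells could vary so as well, so the correlation does not decide between these. The mean differences of 4 pigment and 5 visual cycle genes were -0.65 and -1.13 at day 28, and -0.94 and -0.95 at day 84. A change of the list's transcripts in the cells stays open and cannot be settled from whole tissue. Exact permutation within each day gave p = 0.005 for the mean of days 28 and 84, the smallest that 400 labellings can give. Adjusted over 36 lists this was 0.18, and 400 labellings are too few for 1 list alone to pass. These 2 days were picked after the results were seen, and their possible pairing by title letter was not kept. For the mean of 3 days the permutation p was 0.0255 (0.918 adjusted over 36 lists).

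Crystallins were higher in diabetic than in control retina at day 7 and lower at day 28. Within scans the shift kept its sign, nearest to 0 at 0.526 at day 7, where each scan compares 1 array with 1. At day 28 scans 2 and 6 each held as many diabetic as control arrays. The shift of -0.96 is therefore the same with and without scan as a block by design, which tests nothing. On that day an offset common to all arrays of a scan would cancel. At day 7 scans 3 and 4 each held an array of only 1 of these groups, so scan cannot be fully told apart from group. The spread between arrays was wide. With scan as a block the 95% interval over the arrays was -0.40 to 3.68 at day 7 and -2.80 to 0.89 at day 28. Different amounts of lens tissue with the retinas may account for differences between arrays and for the lower values at day 28. Over 21 arrays the crystallins followed other lens markers with r = 0.909, a test that could have come out at 0. This relation does not account for the size of the day 7 shift, which was 1.57 for crystallins and 0.14 for the lens markers. That crystallin shift was 0.43 without array 3 of the control group, which had a crystallin mean of -2.10 at a lens mean of -0.19. This array had the lowest signal of the 21, with a 75th percentile of 34.4 and 47.2% of probes well above background. The other arrays of its slide were at 127.4 and 125.4. Whether the low signal gave its crystallin mean was not tested. Retinal cells also express crystallins such as Cryab and Cryaa, so a change in the retina stays open, and the lens markers themselves did not pass at day 7 (0.14, adjusted p = 0.758) or day 28 (-0.44, adjusted p = 0.0794). Exact permutation gave p = 0.3 at each of these days, where 20 labellings cannot go under 0.1.

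On array 3 of the control group at day 84, 244 probes lay over 5 log2 units above the other 3 arrays of its slide (at most 14 on any other array). The raised spots were not confined to one part of the array, since 32 of 32 blocks held a raised spot. The median distance from a raised spot to the nearest other was 5.83 grid positions. In 1000 random draws the median was 6.325 (5.10 to 7.62, 66 as short). A mark that raised part of these spots is therefore not excluded. Whether RNA of another tissue was in that pool is not settled. The 23 other probes of 18 of the same genes had a median of -0.76 (-3.05 to 1.62). These leave out any other probe that was itself raised by over 5 log2 units, so genes raised on all their probes could not count. No biological explanation was tested, and the cause stays open. Of the raised probes 111 had a symbol, and 1 was a member of a fixed list.

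Regroupings of the arrays were counted for each result, with the real split among them. In the comparisons of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. For probes the real count was 0 in each, which every split meets (10 of 10), and the highest other split gave 3 at day 7, 0 at day 28, 0 at day 84, 2164 for STZ normoglycemic against control, 0 for diabetic against STZ normoglycemic, and 0, 1893 and 0 for control day 28 against 7, 84 against 7 and 84 against 28. Counts as high as 2164 and 1893 point to a structure of the samples other than their groups, whose cause was not tested. In the first of these splits scan 3 lay on one side and scan 5 on both; in the second no scan lay on both sides, and the 75th-percentile signals were 34.4 to 307.7 on one side and 350.3 to 836.2 on the other. No probe passed in limma in either comparison with scan as a block (1071 and 2705 with an unadjusted p under 0.05). For lists, in the same order, the real counts were 3, 8, 1, 1, 2, 0, 0 and 1, the highest others 10, 6, 1, 9, 9, 6, 2 and 3, and the splits with as many 5, 1, 4, 10, 9, 10, 10 and 5 of 10. For control day 84 against 28, where title letters may pair the arrays, 4 splits part all 3 pairs, the real one among them (highest other 3 lists), and the other 6 part 1 pair (highest 1).

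A real count of 0 is met by every split and decides nothing about chance. This holds for probes in the mean of 3 days and in the changes from day 7 to 28, 7 to 84 and 28 to 84 (100 of 100 each, highest others 0, 4, 3 and 2), and for lists from day 28 to day 84 (100 of 100, highest other 6). For the mean of 3 days 55 of 100 splits gave as many lists (real 2, highest other 7), and for the change from day 7 to day 84 21 of 100 (real 3, highest other 6), so chance cannot be excluded. For the change from day 7 to day 28 as many lists came in 3 of 100 (real 8, highest other 10). That share excludes chance for the count only when taken alone: adjusted over the 6 shares of this kind it is 0.18, and with an estimated correlation and with fry 0 lists passed. Chance cannot be excluded for the correlations between days either, with 42, 11 and 45 of 100 splits as large for days 7 and 28, 7 and 84, and 28 and 84 (real 0.209, 0.399 and 0.179, highest others 0.560, 0.439 and 0.706).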

How the results depend on the processing

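Fits with scan or slide as a block for the lists, with only the arrays of the groups compared for the lists, without array 3 of the control group at day 84 in a blocked fit, and on scans 6 and 7 alone were chosen after seeing the data. The cause was not tested for any change below, except where the setting itself gives it.

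The count of 0 probes held in most alternatives, in 23 of 25 at day 7, 25 of 27 at day 28, 22 of 27 at day 84 and 34 of 37 for the mean of 3 days. Array weights (0.145 to 10.5 per array, estimated gene by gene, of uncertain meaning with 3 arrays per group) gave 1 probe at day 7, 87 at day 28, 92 at day 84, 178 for the mean, 1 for the change from day 7 to day 84, 40 from day 28 to day 84, and 17252, 12252 and 106 for control day 28 against 7, 84 against 7 and 84 against 28. Title letter as a fixed replicate block gave 452 and 2611 for control day 28 and day 84 against day 7. Arrays of 1 letter share it across days within a treatment. After group means were removed, such pairs of days 7 and 28 correlated over 0.1 in 2 of 3 in control retina (lowest -0.02) and 2 of 3 in diabetic retina (lowest -0.02), and those of days 7 and 84 in 0 of 3 (lowest -0.33) and 2 of 3 (lowest -0.20), so the letters are not taken to pair day 7 with a later day. Between days 28 and 84 they are taken as a possible pairing. The letter block there brought the respiratory chain past the threshold in control retina and changed no other call of probes or lists with the preset correlation. Scan as a random block gave 1 for the mean. Scan as a fixed block without array 3 of the control group at day 84 gave 3 at day 84, 1 for day 7 to day 84 and 2 for day 28 to day 84, and scans 6 and 7 alone without that array gave 12 at day 84. An unadjusted p under 0.05 with at least 1.5-fold, which corrects for no multiple testing, gave 639, 42, 538 and 646 for days 7, 28, 84 and their mean, 873 for STZ normoglycemic against control, 368 for diabetic against STZ normoglycemic, 127, 205 and 84 for the changes between days 7 and 28, 7 and 84, and 28 and 84, and 4293, 5703 and 330 for the control days. Of the fits that left out 1 array, only that without array 2 of the control group at day 84 gave any (0 to 2 at day 84, 0 to 0 elsewhere).

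Counts of lists moved more. With an estimated correlation 2 of 8 lists passed at day 28 and 0 in each other comparison, and fry gave 0 in direction and 0 mixed throughout. Normexp gave 6 at day 7, 3 at day 84, 6 for the mean, 0 for STZ normoglycemic against control, 4 for day 28 to day 84, and 10, 1 and 3 for the control days. Quantile normalization gave 1 at day 7, 1 for the mean and 3 for day 7 to day 28. The mean of all probes of a gene gave 4 for diabetic against STZ normoglycemic and 1 for control day 84 against 7. No filter gave 1 for day 28 to day 84, 3 for control day 28 against 7 and 3 for 84 against 28. Scan as a fixed block gave 1 at day 7, 4 at day 84, 8 for diabetic against STZ normoglycemic, 3 for day 28 to day 84 and 1 for control day 84 against 7, and together with an estimated correlation 0 in each of the comparisons it could be fitted to. Slide as a fixed block gave 5 at day 7, 5 at day 28, 4 at day 84, 9 for STZ normoglycemic against control, 5 for diabetic against STZ normoglycemic and 2 for control day 84 against 7. Only the arrays of the groups compared gave 4 at day 84, 0 for STZ normoglycemic against control and 1 for control day 84 against 7. Scan as a block without array 3 of the control group at day 84 gave 1 at day 7, 5 at day 84, 8 for diabetic against STZ normoglycemic, 2 for day 28 to day 84 and 3 for control day 84 against 7. Scan and slide as fixed blocks could not be fitted for control day 28 against 7 and 84 against 28.

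Leaving out 1 array leaves 2 in its group. The counts of lists then ranged over 1 to 3 at day 7, 4 to 7 at day 28, 1 to 3 at day 84, 1 to 3 for the mean, 0 to 3 for STZ normoglycemic against control, 0 to 7 for diabetic against STZ normoglycemic, 4 to 8, 2 to 7 and 0 to 3 for the changes from day 7 to 28, 7 to 84 and 28 to 84, and 0 to 2, 0 to 2 and 0 to 4 for control day 28 against 7, 84 against 7 and 84 against 28. The arrays whose removal moved a count were arrays 1, 2 and 3 of the STZ normoglycemic group, 1, 2 and 3 of control day 7, 1, 2 and 3 of control day 28, 1, 2 and 3 of control day 84, 1 and 3 of diabetic day 7, 1, 2 and 3 of diabetic day 28 and 1 of diabetic day 84. Calls of single lists were also lost without array 2 of diabetic day 7 and array 3 of diabetic day 84. Pigment epithelium markers passed in each such fit at day 28 (6 of 6), day 84 (6 of 6), the mean (18 of 18) and the changes from day 7 to 28 and 7 to 84 (12 of 12 each).

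Some shifts turned. Immediate early genes at day 28 were at -0.20 without array 1 of the diabetic group and -0.17 without array 2 of the control group (-0.20 to 0.44 over the fits that left out 1 array). Extracellular matrix at day 28 was at -0.091 without array 2 and -0.030 without array 3 of the control group (-0.091 to 0.42), and -0.077 with slide as a fixed block. The p53 list at day 28 was at -0.0054 without array 1 of the diabetic group (-0.0054 to 0.17). Crystallins of STZ normoglycemic against control were at -0.38 without array 3 of the control group and -0.44 without array 3 of the STZ normoglycemic group (-0.44 to 1.61). The respiratory chain was at -0.013 with slide as a block between diabetic and STZ normoglycemic retina, and its change from day 7 to day 28 was at 0.086 without array 1 of control day 28, 0.035 without array 2 of diabetic day 28, 0.0012 without array 3 of control day 7 (-0.52 to 0.086) and 0.048 with slide as a fixed block.

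On probes well above background on all 21 arrays the correlation between the effects of days 7 and 28 was -0.083 and that of days 7 and 84 was 0.021. Leaving out 1 array gave -0.182 to 0.355 for days 7 and 28 (lowest without array 1 of control day 28), -0.015 to 0.537 for days 7 and 84 and -0.051 to 0.336 for days 28 and 84 (both lowest without array 1 of control day 84). The correlation of the diabetic and STZ normoglycemic effects ranged over 0.283 to 0.746 (lowest without array 3 of diabetic day 7). Of 11351 alternative values of the named genes, 302 (2.66%) changed sign and 0 passed in the settings run for them; the values under array weights stand apart from these.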

Other observations

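In control retina, blood and red cell markers had lower values at later days, mainly on the arrays of scans 6 and 7. The score of the list was 1.08 to 1.43 on the control arrays of day 7, 0.82 and 0.55 on those of days 28 and 84 in scans 2 and 4, -0.77 and -0.96 on those of day 28 in scan 6, and -1.05 and -1.64 on those of day 84 in scan 7, the last on array 3, which stands apart. The diabetic arrays of scans 6 and 7 were at -1.04 to -0.28. All 11 members lay lower at day 84 than at day 7 (mean -2.01) and 10 of 11 at day 28 (-1.6), and neither difference passed in camera (adjusted p = 0.156 and 0.094). With scan as a block the shift from day 7 to day 84 was -1.49 (adjusted p = 0.014, and 0.994 with an estimated correlation as well), and -1.24 without array 3 of day 84 (adjusted p = 0.028). No scan held control arrays of both days, so these blocked shifts rest on links through arrays of other groups. The score of skeletal muscle and ocular surface markers moved the same way on these control arrays. It was 0.99 to 1.86 at day 7, 0.98 and 1.19 in scans 2 and 4, -0.62 and -0.86 in scan 6, and -0.81 and -1.47 in scan 7. The 75th-percentile signals of these control arrays were 34.4 to 350.3 at day 7, and 306.8 and 143.7 in scans 2 and 4. In scans 6 and 7 they were 815.9 to 881.3. Values are relative to that percentile, so for both lists day is not told apart from signal level. Inflammatory mediators were at -1.01 at day 28 against day 7 (15 of 17 lower, adjusted p = 0.094) and extracellular matrix genes at -0.84 (23 of 25 lower, adjusted p = 0.131). From day 28 to day 84 microglia and macrophage markers were at -0.43 (18 of 21 lower, adjusted p = 0.0809).

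With scan as a block, further lists passed between diabetic and STZ normoglycemic retina at day 7 that had not passed without it. Crystallins were at 1.51 (adjusted p = 3.3e-11), pigment epithelium markers at 0.39 (4.2e-04), the retinoid cycle at 0.24 (4.6e-04) and lens markers at 0.30 (0.0174), and lower were cone genes at -0.51 and vascular cells at -0.38 (0.0464 each). None of these passed with an estimated correlation as well (adjusted p = 0.544 to 0.742). Among the members, the cone channel subunit Cngb3 was at -2.04 ± 0.78 without the block, and Rgr and Lrat at 0.80 ± 0.40 and 0.88 ± 0.46; in STZ normoglycemic against control retina Rgr and Lrat were at -0.73 ± 0.40 and -0.84 ± 0.46, and the muscle and corneal genes Tnnc2 and Krt12 at -2.32 ± 1.52 and -2.53 ± 1.45.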
